A study of Homo sapiens with 6 samples.

How the data were processed

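RNA was measured in NCI-H295A cells, an established human adrenocortical carcinoma line, on 6 Affymetrix oligonucleotide arrays, 3 from control plates and 3 from plates kept for 18 h with 8-Br-cAMP at 1 mM. Groups and sample numbers 1 to 3 were taken from the sample titles. The labels do not say whether the plates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

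The deposited values are signal intensities on a linear scale, 1 per probe set and array, made with GCOS 1.3 per the labels' protocols. Detection calls were not used here. The 2% trimmed mean of every deposited column lay between 249.996 and 250.155, within the 5% set beforehand for treating arrays as already scaled, so the deposited intensities were used without further normalization. A scaling to a common mean fixes the total signal of an array, so a change in the same direction of most transcripts would not be seen. The table holds 22277 probe sets, of which 62 are array controls and 22215 were analysed. GEO's platform annotation gave 1 symbol for 19064 of these and several for 1043, and 2108 are not listed in it. Gene IDs of 19052 single-symbol probe sets matched the current gene table, with 0 symbols changed. No gene was named from a probe set with several symbols. CYP21A2 has only such a probe set and MAPK14 has no listed one, so neither is analysed here.

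Intensities were taken to log2. Probe sets with a mean log2 signal above the 40th percentile, 5.51 on the log2 scale or a signal of 45.5, were kept, which left 13329 probe sets and, at 1 probe set per gene (the one with the highest mean), 7927 genes. Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend) as two-sided tests, with Benjamini-Hochberg adjustment over the kept probe sets and a threshold of 0.05. Unless another tool is named, each adjusted p is limma's. The design fixed before the data were examined had no block, and a fit with the sample number as a replicate block was the alternative set with it. The deviations of same-numbered arrays from their group means correlated at 0.603, 0.378 and 0.538 across kept probe sets for numbers 1, 2 and 3, all over the 0.1 set beforehand, so the numbers were taken to pair the samples. The pairing comes from the data and not from the labels, and it mainly parts number 1 from the others, since control 3 correlated slightly better with 8-Br-cAMP 2 (0.547) than with 8-Br-cAMP 3 (0.538). Log2 differences are the same in both fits and only their errors differ. The fit with the replicate block is called the paired fit.

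Gene lists, 21 with 499 genes in all, were fixed before the data were examined. Each list with at least 5 measured genes was tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and fry, which tests a list against no change and not against other genes, as alternatives. One of these lists was tested with the rest and enters their adjustment, but it and the genes named from it are not reported here. Named genes follow a rule fixed beforehand: the 5 largest rises and 5 largest falls that pass with no overlap between groups and both means above the filter level, per list the 2 passing members with the smallest adjusted p, the 3 smallest adjusted p among genes that rose from a control mean below the filter level, a fixed set of steroidogenic and signalling genes, and the 5 smallest unadjusted p where none passes. Since none passed without the block, the rule was applied to the paired fit as well, a choice made after that count was seen. Genes named outside the rule were chosen after their values were seen.

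Alternatives covered quantile normalization, a common median, no filter and a stricter filter at the 60th percentile, a floor at the 20th percentile, a pseudocount of 16, eBayes without a trend and with robust variances, the replicate block, an unmoderated test, other list tests, and each array left out. Scaling on 18 hybridisation spike-in probe sets, both number 1 arrays left out, a block parting number 1 from numbers 2 and 3, and each alternative combined with the block were added after the data were seen. The fits were tested on simulated data, 5 runs with 200 of 13329 probe sets changed and the measured pair effects and residual spread. The fit without the block recovered 0% of 2-fold, 12.2% of 4-fold and 42.4% of 8-fold changes. The paired fit recovered 0%, 36.1% and 60.9%, with 0.971% of the paired calls false on average. Simulated pair effects were shared exactly within a pair, and the residual spread of a probe set was the same on all arrays. The measured arrays need not meet this, and their share of changed probe sets may differ from 200 of 13329. The recovered shares therefore need not hold for the measured arrays, and 0.971% does not give the false share among the measured calls. A list of 20 genes raised by 1 on the log2 scale was called in 5 of 5 runs by camera with the preset correlation in either fit. With the estimated correlation it was called in 5 of 5 runs without the block and in 0 of 5 with it, and 0 of 100 unchanged lists were called. Genes were independent in the simulation, so it does not test the preset correlation.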

Results

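Transcript levels were compared between NCI-H295A cells left without treatment and cells kept for 18 h with 8-Br-cAMP at 1 mM, with 3 arrays in each group. NCI-H295A is a steroid-producing human adrenocortical carcinoma line, and 8-Br-cAMP is a cell-permeable cAMP analogue that stands in for the signal of the pituitary hormone ACTH. The series concerns the phosphorylation of P450c17, the CYP17A1 product that catalyses the hydroxylase and lyase steps towards androgens, so kinases and phosphatases are of interest beside the steroidogenic genes.

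The arrays numbered 1 stood apart from the rest in both groups. The actin control 3'/5' signal ratio, a sign of RNA integrity, was 5.72 on control 1 and 38.8 on 8-Br-cAMP 1, against 1.93 to 2.41 on the other 4 arrays. The GAPDH ratio was 1.79 and 4.29 on the same arrays and 1.05 to 1.17 on the others. Across kept probe sets, the first principal component (54.1% of variance) parted the number 1 arrays from the others, and the second (27.1%) parted treated from control arrays. Log2 signals correlated at 0.980 between 8-Br-cAMP 2 and 3, at 0.961 between controls 2 and 3, and at 0.776 between 8-Br-cAMP 1 and 8-Br-cAMP 2. Across probe sets, which are not independent replicates, log2 differences correlated at 0.749 between pairs 2 and 3, but at 0.215 and 0.287 between pair 1 and those pairs.

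**Figure D1:**
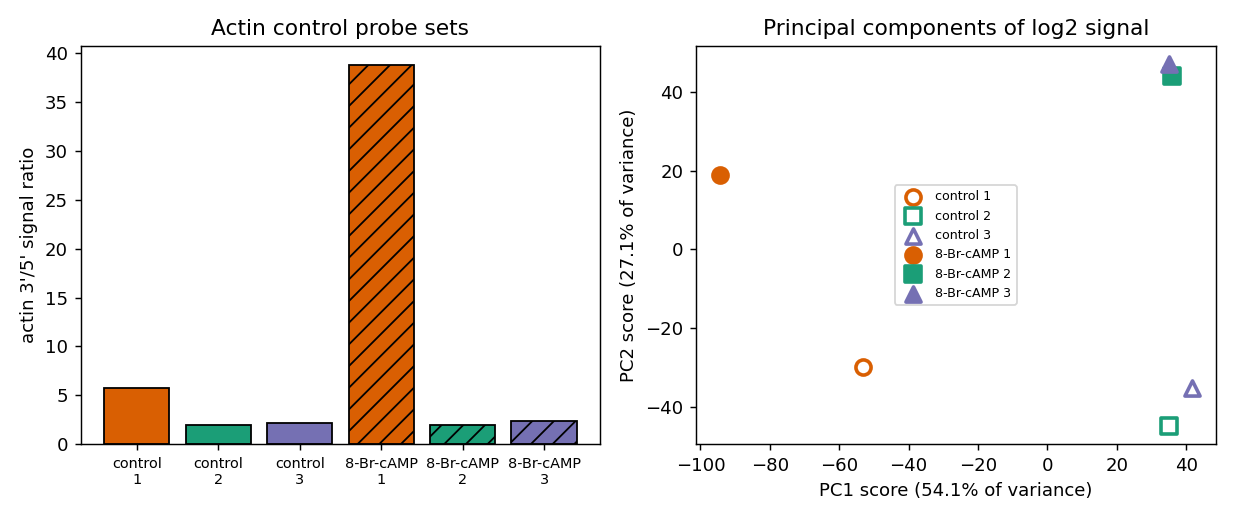
Left, the 3'/5' signal ratio of the actin control probe sets (bars from 0, 1 per array, hatched for 8-Br-cAMP); right, scores of the 6 arrays on the first and second principal components of log2 signal, with open symbols for control and filled for 8-Br-cAMP. 8-Br-cAMP 1 has a ratio of 38.8 and both number 1 arrays lie below 0 on the first component.

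The treatment response included higher transcripts of some genes of steroid synthesis, cholesterol synthesis and cAMP-responsive transcription factors, and lower transcripts of genes such as DNAJC15, IQGAP2 and NRCAM. In the paired fit, 428 of 13329 probe sets changed, 207 up and 221 down, and 421 of them by at least 2-fold (201 up, 220 down). They stood for 292 genes, 137 higher and 155 lower. Without the block, limma called 0 probe sets (smallest adjusted p 0.0511). At an unadjusted p under 0.05 there were 1474, where 666 are expected by chance. Splits of the arrays that cross the groups gave 1220 to 2156 with both number 1 arrays on the same side. They gave 11 to 502 with the number 1 arrays apart, as these are in the labelled split. An excess over 666 thus also arose where the number 1 arrays were grouped together. With them apart, only the labelled split exceeded 666, and the splits are too few for a share under 0.05. The unmoderated test called 1, FAM13A (log2 difference -0.95, adjusted p = 0.00642), named after its value was seen. Of the 428 paired calls 347 had no overlap between groups. Over all tested probe sets 18.5% had none, where chance gives 10% for exchangeable arrays, which the differences between the sample numbers put in doubt. Still without the block, 58 passed without control 1 and 285 without 8-Br-cAMP 1, and 0 without any of the other 4 arrays. With both number 1 arrays left out, 4103 probe sets passed without a block, among them all 428 in the same direction. That is no independent check, since its arrays also entered the paired fit and all 428 have the same sign in all 3 pairs. It rests on arrays 2 and 3, which correlate at 0.961 in controls and 0.980 after 8-Br-cAMP. Its p-values and calls, here and below, may therefore measure only technical spread. In that fit 1016 of all 7927 genes rose and 1627 fell, the background against which its list counts below are to be read. The median log2 difference of all kept probe sets was -0.13 as deposited, -0.03 after quantile normalization, 0.09 with a common median and -0.50 on the spike-in scale. The up and down split of paired calls moved with it, from 207 and 221 to 103 and 39 with a common median and to 103 and 961 on the spike-in scale. These spike-ins report on hybridisation and scanning, so the 961 falls do not show a general decrease of transcripts. Their mean log2 signal was highest on 8-Br-cAMP 1 (11.42).

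CXCR4, a chemokine receptor, had the largest rise among passing genes with no overlap and both group means above the filter level, from a log2 signal of 6.12 ± 2.21 (SD, n = 3) to 11.34 ± 0.32, or 37.2-fold (paired adjusted p = 0.0147), while its other 2 kept probe sets rose by 2.90 and 3.12 on the log2 scale and did not pass. SPRR1B and SPRR3, small proline-rich proteins of the epithelial cell envelope, rose 24.1-fold and 22.8-fold (both adjusted p = 0.00679). NPTX2, a neuronal pentraxin, rose 13.3-fold (adjusted p = 0.0395), and EGR1, an immediate early transcription factor, rose 13.0-fold with the smallest adjusted p of the paired fit (log2 difference 3.70, SE 0.19, adjusted p = 0.00486). DNAJC15, a mitochondrial co-chaperone, fell by 4.61 on the log2 scale (SE 0.44, adjusted p = 0.0109). Also among the largest falls were IQGAP2, a scaffold protein of the cytoskeleton (-3.45), the annexin ANXA4 (-3.22), the presynaptic scaffold gene PCLO (-3.16) and the cell adhesion gene NRCAM (-2.99, log2 differences), with paired adjusted p between 0.00679 and 0.0290. From a control mean below the filter level, MMP17 rose 8.88-fold, NR4A3 14.5-fold and the chemokine CCL22 39.2-fold, and folds from such low signals are imprecise, as are those of AQP3 and VWF, also low in controls, and of NAALAD2, low after 8-Br-cAMP. The folds of CXCR4 and SPRR3 are imprecise as well, since their signals on controls 2 and 3 lay below the filter level. These were 36 and 23.5 for CXCR4, and 27.5 and 38.2 for SPRR3. Their control means lay above that level only because of control 1, at 400.4 for CXCR4 and 119 for SPRR3. With 1 pair left out the log2 differences ran from 4.53 to 6.29 for CXCR4, 3.10 to 4.87 for NPTX2 and 4.60 to 6.16 for CCL22. They ran from 4.33 to 4.92 for SPRR1B, 4.16 to 4.95 for SPRR3, -5.33 to -4.21 for DNAJC15 and -3.98 to -2.71 for PCLO. Single pairs differed more than these ranges. NPTX2 differed by 1.45 in pair 1, and by 4.75 and 4.98 in pairs 2 and 3. CXCR4 differed by 3.07 in pair 1, and by 5.99 and 6.60 in pairs 2 and 3, and PCLO by -1.51, and by -4.05 and -3.92. The NPTX2 call was lost in 4 of 12 alternatives combined with the block. Without the block the smallest unadjusted p belonged to SEMA5A (-2.77), NRCAM (-2.99), AQP3 (3.50), NAALAD2 (-3.23) and MMP17 (3.15, log2 differences), all at an adjusted p of 0.0511. These 5 genes passed the paired fit. Of the 37 named genes that passed it, 20 had several kept probe sets, which in all 20 moved in 1 direction. In 8 of these (NRCAM, CXCR4, NR4A3, NR4A1, GRK5, FST, CALR and COL3A1) another kept probe set did not pass.

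Steroidogenic genes moved in both directions, with more of them higher after 8-Br-cAMP. Of 17 measured steroidogenic enzymes and carriers, 5 rose (CYP11A1, CYP11B1, CYP17A1, FDX1, PAPSS2), 1 fell (AKR1C3) and 11 did not pass, and adjusted over the list alone 10 rose and 4 fell. CYP11B1, which encodes 11β-hydroxylase, rose by 2.59 on the log2 scale (SE 0.20, adjusted p = 0.00805), from a log2 signal of 8.37 ± 1.20 to 10.96 ± 1.39 (SD, n = 3). CYP11A1, the side-chain cleavage enzyme that makes pregnenolone, rose by 2.31 (SE 0.20, adjusted p = 0.00901), and FDX1, the ferredoxin that passes electrons to mitochondrial P450 enzymes, by 2.17 (SE 0.19, adjusted p = 0.00879). CYP17A1 rose by 1.12 (SE 0.17, 95% interval 0.70 to 1.53, adjusted p = 0.0287), but its call was lost in 6 of 12 alternatives combined with the block, over which its adjusted p ran from 3.22e-06 to 0.133. Signals of these 4 genes, STAR and HSD3B2 were highest on the number 1 array of each group, with CYP11B1 at 851.5 on control 1 against 236.4 and 179.9 on controls 2 and 3. STAR, the carrier of cholesterol into mitochondria, differed by 0.98 (0.49 to 1.46, adjusted p = 0.0568), the P450 oxidoreductase gene POR by 0.84 (0.41 to 1.27, adjusted p = 0.0592) and HSD3B2 by 1.22 (0.38 to 2.06, adjusted p = 0.119), and none of these passed the paired fit. CYB5A, the cytochrome b5 that aids the lyase step, differed by -0.89 (-1.53 to -0.25, adjusted p = 0.130), while another of its 3 probe sets fell by 1.72 (adjusted p = 0.0468). With both number 1 arrays left out, 8 of the 17 genes rose and 4 fell. STAR (1.21), POR (0.84) and HSD3B2 (1.78) were then higher and CYB5A (-1.0, log2 differences) lower, at adjusted p between 3.15e-05 and 0.0223. These p-values rest on the closely alike arrays 2 and 3, whose spread may be technical. As a set the list shifted up in camera (adjusted p = 0.0152 without and 0.000154 with the block). With an estimated correlation the adjusted p was 0.588 and 0.310, and with fry 0.558 and 0.0718. Fry tests a list against no change and not against other genes. No list passed either of these alternatives in either fit, while with both number 1 arrays left out 8 of 20 lists passed fry, this one among them (adjusted p = 0.0221), and 0 passed with an estimated correlation.

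**Figure D2:**
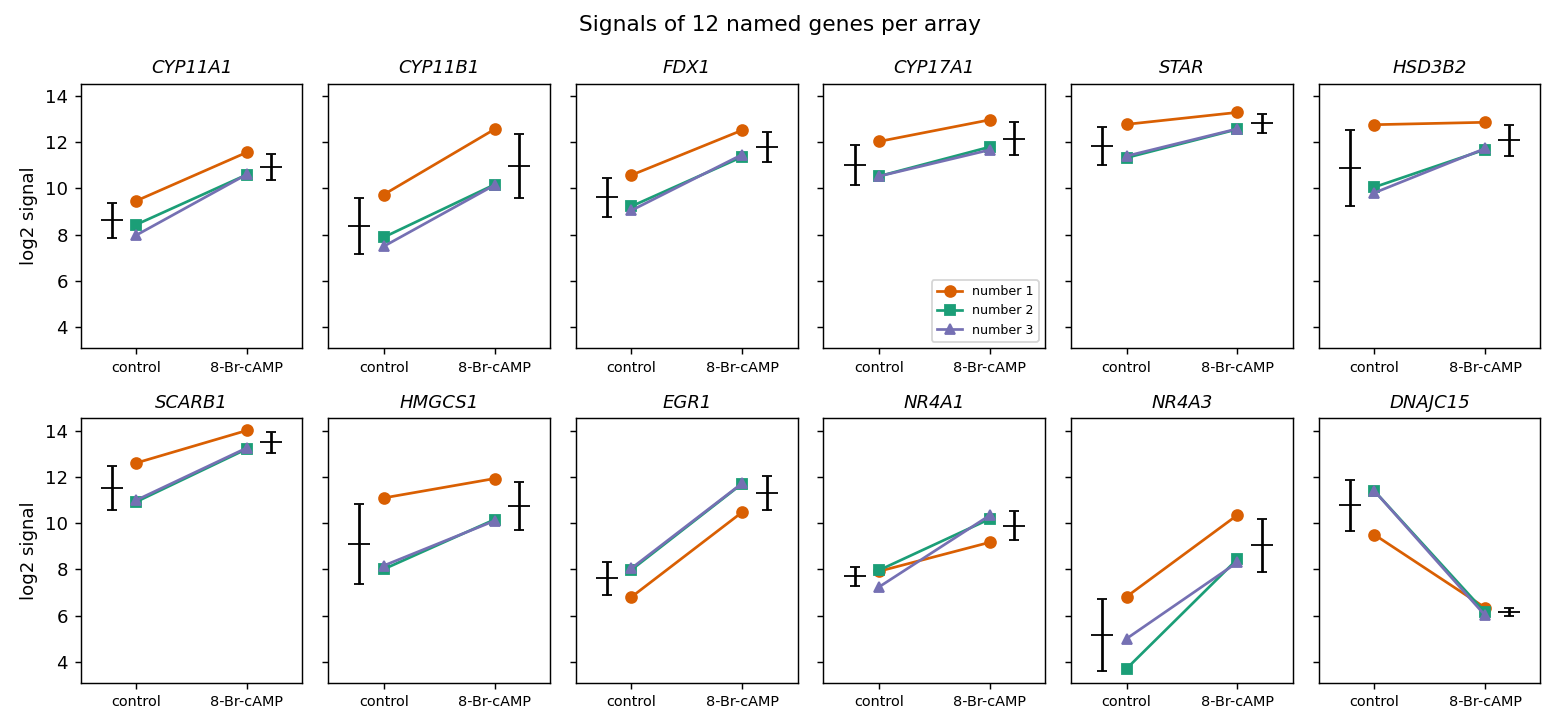
Log2 signal (y axis) of 12 named genes on control and 8-Br-cAMP arrays, with coloured lines joining same-numbered arrays and black bars giving the group mean ± SD (n = 3). HSD3B2 differs by 0.10 in pair 1 and by 1.63 and 1.92 in pairs 2 and 3, while EGR1 differs by 3.68 to 3.74 in the 3 pairs.

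Of 16 measured cholesterol synthesis genes 5 rose (HMGCS1, HSD17B7, INSIG1, MSMO1, NSDHL), 0 fell and 11 did not pass, with 10 higher when adjusted over the list alone. INSIG1 is a sterol-regulated inhibitor of the pathway, and the others are enzymes. NSDHL rose by 2.42 (SE 0.27, adjusted p = 0.0132) and HMGCS1 by 1.64 (SE 0.29, adjusted p = 0.0402), a call lost in 4 of 12 alternatives. With both number 1 arrays left out, 12 rose and 1 fell. Signals of both genes were higher on the number 1 arrays of each group, with HMGCS1 at 2185.3 on control 1 against 257.4 and 286.3 on controls 2 and 3. The list shifted up in camera (adjusted p = 0.000121 without and 5.37e-09 with the block), with an adjusted p of 0.588 and 0.310 with an estimated correlation. Of 10 genes of cholesterol uptake, transport and storage 1 rose, SCARB1, the receptor that takes up lipoprotein cholesterol (1.99, SE 0.22, adjusted p = 0.0142). The list did not pass (paired camera adjusted p = 0.0969). With both number 1 arrays left out, 6 of the 10 rose and 1 fell. The list then passed camera (adjusted p = 0.00633) but not with an estimated correlation (0.277). The list's median difference was -0.24 in pair 1, and 0.59 and 0.74 in pairs 2 and 3.

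The CREB and CREM target genes that passed the paired fit were all higher. Of 15 measured, 6 rose (EGR1, INHA, JUNB, NR4A1, NR4A3, SIK1), 0 fell and 9 did not pass, with 8 higher when adjusted over the list alone, and 11 higher and 1 lower with both number 1 arrays left out. The nuclear receptor NR4A3 rose by 3.86 (SE 0.34, adjusted p = 0.00893), and its relative NR4A1 by 2.19 (SE 0.35, adjusted p = 0.0313). With 1 pair left out these ran from 3.42 to 4.14 for NR4A3 and from 1.74 to 2.66 for NR4A1. Camera gave an adjusted p of 1.89e-06 without and 2.10e-08 with the block, and 0.288 and 0.310 with an estimated correlation. NR4A1 and NR4A3 were also the 2 genes that rose among 10 ACTH receptor and adrenal transcription factor genes, a list that did not pass (paired adjusted p = 0.342).

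Of 137 measured genes of 5 kinase and phosphatase lists 5 passed the paired fit (3.6%), a share like that of all genes (292 of 7927, 3.7%), and with both number 1 arrays left out 46 passed (33.6%, against 33.3% of all genes). In the paired fit 0 of 23 genes of protein kinase A, adenylyl cyclases and phosphodiesterases and 0 of 31 serine/threonine phosphatases and PP2A regulators passed, with 2839 of all probe sets at an unadjusted p under 0.05 in that fit. Adjusted over the list alone, 1 of the phosphatase genes rose and 1 fell. With both number 1 arrays left out, 4 rose and 4 fell on the first of these lists, and 1 rose and 6 fell on the other. MAPK13, which encodes a p38 kinase, was the 1 of 23 MAP kinase cascade genes to rise (1.05, SE 0.20, adjusted p = 0.0474). Of these 23 genes, 2 rose and 8 fell with both number 1 arrays left out. The MAPK13 call was lost in 5 of 12 alternatives (adjusted p up to 0.267). Among 49 other serine/threonine kinases GRK5 rose by 1.79 (adjusted p = 0.0368), while SGK1 fell by 1.28 (adjusted p = 0.0262, lost in 4 of 12 alternatives) and CDK5, named after its value was seen, fell by 1.70 (adjusted p = 0.0423). DUSP5, a nuclear phosphatase of MAP kinases, rose by 1.95 (adjusted p = 0.0282) as the 1 of 11 dual-specificity phosphatase genes. The PP2A inhibitor gene SET differed by -0.23 (95% interval -0.77 to 0.31, adjusted p = 0.612) and the PP2A catalytic gene PPP2CA by 0.07 (-0.45 to 0.59, adjusted p = 0.894). SET differed by 0.29 in pair 1, and by -0.64 and -0.33 in pairs 2 and 3, and passed with both number 1 arrays left out (-0.49, adjusted p = 0.0269). The sign of PPP2CA turned with the scaling. None of these 5 lists passed camera in either fit (paired adjusted p between 0.171 and 0.809). The series' design text selected a change of at least 2-fold with an unadjusted p under 0.05. Under that selection limma without the block gave 880 of 13329 probe sets. It held 9 of 137 measured genes of these lists, 5 higher and 4 lower, a share like that of all probe sets. Besides MAPK13, GRK5, DUSP5 and CDK5, the following were named after their values were seen. Higher were PRKAR2B (1.34, adjusted p = 0.321) and PPP2R1A (1.04, adjusted p = 0.223, log2 differences without the block). Lower were PRKCH (-1.48, adjusted p = 0.182), PRKCZ (-1.06, adjusted p = 0.436) and PPP3CB (-1.01, adjusted p = 0.294).

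Cell cycle genes differed between the pairs. Of 29 cell cycle and DNA replication genes 0 passed the paired fit, although camera placed the list above other genes (adjusted p = 0.0152 without and 0.00495 with the block, and 0.628 and 0.721 with an estimated correlation). The median log2 difference was -0.44 in pair 1, and 0.54 and 0.59 in pairs 2 and 3. The list was higher on control 1 than on controls 2 and 3 (median 1.12, 28 of 29 genes), and on 8-Br-cAMP 1 by a median of 0.20 (18 of 29). With both number 1 arrays left out, 18 of the 29 genes rose and 0 fell.

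**Figure D3:**
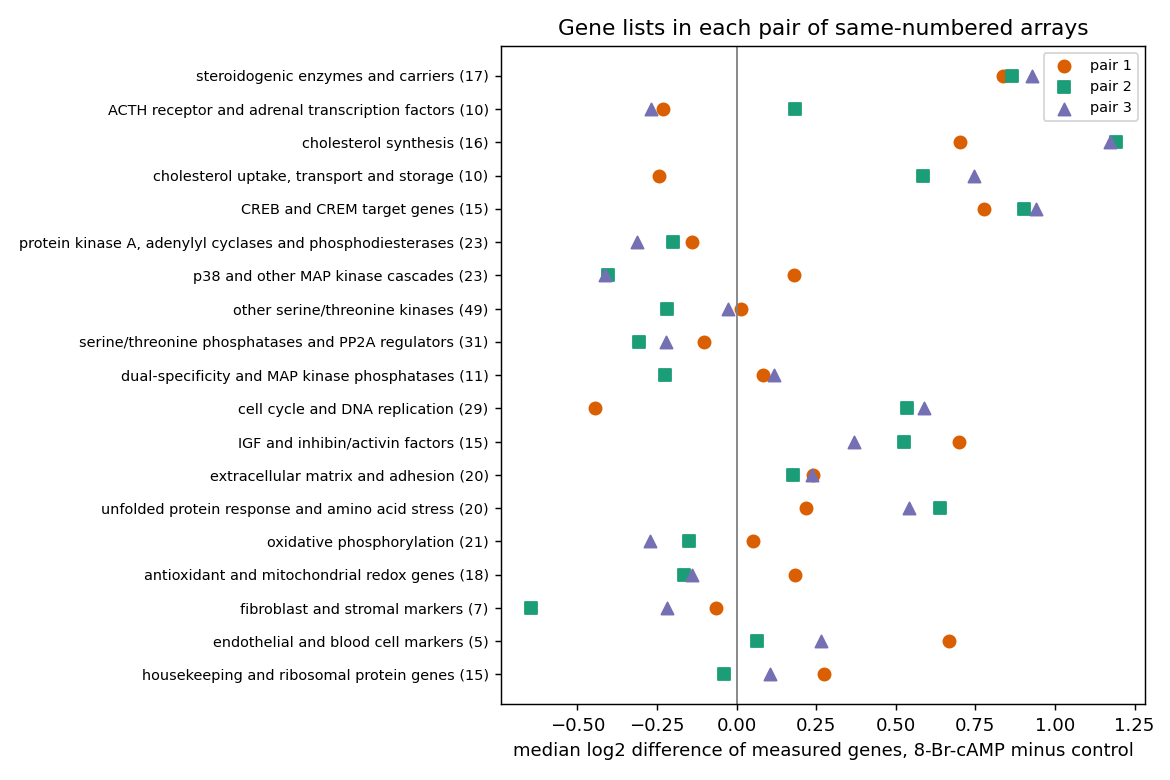
Median log2 difference (8-Br-cAMP minus control, x axis) of the measured genes of each reported list with at least 5, in each pair of same-numbered arrays, with the number of measured genes in brackets. Steroidogenic, cholesterol synthesis and CREB target lists lie above 0 in the 3 pairs. So do the IGF, matrix, unfolded protein response, and endothelial and blood lists. The cell cycle list lies at -0.44 in pair 1 and at 0.54 and 0.59 in pairs 2 and 3.

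Growth factor and matrix genes moved in both directions. Among 15 IGF and inhibin/activin genes 4 rose (FST, IGF1R, INHA, IRS2) and 2 fell (BMP4, IGFBP2). FST, which encodes the activin-binding follistatin, rose by 1.67, and the insulin receptor substrate IRS2 rose by 1.52 (both adjusted p = 0.0144). The list passed camera with the block (adjusted p = 0.0491) and not without it (0.0561), and had an adjusted p of 0.472 with an estimated correlation and the block. Among 20 extracellular matrix and adhesion genes 4 rose (COL4A1, COL4A2, THBS2, TIMP1) and 3 fell (CCN2, COL3A1, LAMB1), with COL4A1, a basement membrane collagen, up by 1.81 (adjusted p = 0.0224) and CCN2 down (-1.96, adjusted p = 0.0231). That list passed without the block (adjusted p = 0.0479) and not with it (0.0858), and had an adjusted p of 0.469 with an estimated correlation and no block. In the IGF list, and likewise in the matrix list, 8 genes rose and 3 fell with both number 1 arrays left out. In the unfolded protein response and amino acid stress list 1 of 20 genes rose, the chaperone gene CALR (1.22, adjusted p = 0.0262). There were 10 higher and 2 lower when adjusted over the list alone, and 13 and 3 with both number 1 arrays left out. The list shifted up (adjusted p = 0.0152 without and 0.000220 with the block, and 0.588 and 0.310 with an estimated correlation). The metallothionein genes MT1X (1.41) and MT2A (1.40, log2 differences, adjusted p = 0.0200 and 0.0238) rose among 18 antioxidant genes, where the peroxiredoxin gene PRDX3 fell. The antioxidant list did not pass (paired adjusted p = 0.710), nor did 21 oxidative phosphorylation genes (0.671), of which 0 changed, or 15 housekeeping and ribosomal protein genes (0.312), of which 0 changed. Among the oxidative phosphorylation genes 4 fell and 0 rose with both number 1 arrays left out, where 1627 of all 7927 genes fell and 1016 rose. Of markers of other cell types, COL3A1 fell among 7 fibroblast genes (-1.35, adjusted p = 0.0485, lost in 5 of 12 alternatives) and VWF, an endothelial clotting factor, rose among 5 endothelial and blood genes (3.12, adjusted p = 0.0493, 2.44 to 4.06 with 1 pair left out, with its call lost in 4 of 11 alternatives). Neither list passed (paired adjusted p = 0.324 and 0.171), and 0 of 4 measured chromaffin genes changed, too few for a list test.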

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

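The tests of exchanged arrays, of rises above GAPDH and of loss on 8-Br-cAMP 1 were chosen after related values were seen, and the others before. The test of loss on 8-Br-cAMP 1 replaced one written before, the percentile of the cell cycle list's pair 1 median among random lists (1.14), which also depends on control 1. A test of probe sets over 8-fold higher on both number 1 arrays (0.0525% of those kept) was dropped after its value was seen because it could hardly fail. Hybridisation spike-ins, which report on hybridisation and scanning and enter no main comparison, were higher on every 8-Br-cAMP array than on any control array, by 0.37 in mean log2 signal (11.17 ± 0.22 against 10.80 ± 0.12, SD, n = 3, exact permutation p = 0.1, two-sided, the smallest possible here). The actin 3'/5' ratio of 38.8 on 8-Br-cAMP 1 was also above every control array.

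The arrays numbered 1 stood apart and pair 1 correlated weakly with the other pairs. An exchange of the control and treated arrays numbered 1 is argued against, since with their labels exchanged the paired fit called 0 probe sets instead of 428. RNA degradation may account for part of the pattern: probe sets of 1 gene, which lie at different distances from the 3' end, disagreed more, with 0.469 of the variance between genes for control 1 against controls 2 and 3 and 0.752 for the treatment difference in pairs 2 and 3, a ratio of 0.624. The share was 0.384 for 8-Br-cAMP 1 against 8-Br-cAMP 2 and 3 (ratio 0.510) and 0.294 for the treatment difference in pair 1 (ratio 0.391). Differences that rest on single arrays also carry more noise, which lowers the share. The first ratio, for which bounds were set beforehand, lies between them, so degradation as the whole cause stays open. The GAPDH 3' control probe set rose 2.24-fold and 2.78-fold on the number 1 arrays. In 2.30% of kept probe sets both number 1 arrays exceeded the others by more than that. By the same folds it was 0% for numbers 2 and 3, which is no background, since arrays 2 and 3 are closely alike. How far rescaling after a loss can raise a probe set is not known, so that stays open as well. A difference between cultures or array batches stays open because the labels name none and no biological explanation was tested.

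Cell cycle genes were higher after 8-Br-cAMP in pairs 2 and 3 and not in pair 1. Loss of signal on 8-Br-cAMP 1 as the whole cause would place the list about 1.01 lower on that array than on 8-Br-cAMP 2 and 3. The list's median was 0.20 higher there (95% interval -0.17 to 0.54 over genes, which may not be independent). That prediction holds only if the number 1 arrays do not otherwise differ for the list. Control 1 was itself higher than controls 2 and 3 by a median of 1.12, and a loss from a like level could give the value seen. The test therefore cannot decide, and a loss on 8-Br-cAMP 1 stays open, alone or beside another cause. Degradation that acts on single probe sets may contribute, since in 43.75% of 16 genes with several probe sets (exact 95% interval 19.8% to 70.1%) these disagreed in sign in pair 1, against 2 genes in pairs 2 and 3, although differences nearer 0 also make signs disagree. The controls also differed, with 28 of 29 genes higher on control 1 than on controls 2 and 3 (median 1.12, percentile 100 of 10000 random lists matched on mean signal), so a different growth state of that plate stays open, and no biological explanation was tested.

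For the counts of calls, splits of the 6 arrays are too few for a share under 0.05. Without the block the labelled split and the highest of the other 9 among 10 splits each gave 0 calls, with as many in 10 of 10. At an unadjusted p under 0.05 the labelled split gave 1474 probe sets, and the split of controls 1 and 2 with 8-Br-cAMP 1 against the rest gave 2156. Splits with both number 1 arrays on the same side gave 1220 to 2156, and crossing splits with them apart gave 11 to 502. With the block the labelled split gave 428 and the highest of the others that part all 3 pairs 0, with as many in 1 of 4 splits.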

How the results depend on the processing

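Settings that add the block to another choice, the spike-in scaling, the block of number 1 against 2 and 3 and the fit without number 1 were chosen after the data were seen. The count of 0 changed probe sets became 17 with quantile normalization, 17 with a common median, 18 with the stricter filter, 28 with a floor, 28 with a pseudocount of 16, 14 on the spike-in scale and 1 with the unmoderated test, and stayed 0 with no filter, no trend or robust variances. The 2-fold count was the same in each, apart from the unmoderated test, where it was not run, and was 880 by unadjusted limma p and 567 by an unadjusted test on linear signals. With the replicate block the counts were 428 and 421, with number 1 parted from 2 and 3 they were 1294 and 817, and with both number 1 arrays left out 4103 and 1587. Leaving out 1 array gave 0 to 285 calls for either count: 58 without control 1, 285 without 8-Br-cAMP 1 and 0 without any of the other 4. In the paired fit the 428 and 421 calls became 142 and 141 with a common median, 81 and 81 with no trend, and 1064 and 1033 on the spike-in scale. With pair 1 left out, which leaves the closely alike arrays 2 and 3, they became 4680 and 1714. With pair 2 left out both were 342, and with pair 3 left out both were the lowest of the 3, 3.0e2 when rounded (160 rose and 135 fell). The 6 called lists became 3 with quantile normalization (with oxidative phosphorylation lower), 2 with a common median, 10 on the spike-in scale, 0 with an estimated correlation and 0 with fry, and 2 to 7 without 1 array; the lowest, 2, was without 8-Br-cAMP 1. They were 3 without control 2, control 3 or 8-Br-cAMP 3. With the block and quantile normalization 6 were called, 5 of them higher and oxidative phosphorylation lower. In other settings with the block the 6 became 0 with an estimated correlation and 0 with fry, and 8, 4 and 5 with pair 1, 2 or 3 left out. With the estimated correlation the simulated list was not called with the block either, but it was called without it, where these lists were not. That comparison cannot decide, because simulated genes were independent. Without the block the estimated correlation of the 6 lists ran from 0.026 (matrix) to 0.809 (cholesterol synthesis). The cause of these shifts was not tested. The block changed no list's call besides those of the IGF and matrix lists.

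Of the 37 named genes that passed the paired fit, 7 lost their call in at least 4 of the alternatives combined with the block, 13 in 1 to 3 and 17 in none. None of the 37 changed sign, and 17 of 37 passed with no trend, 25 with a common median, 28 on the spike-in scale, 32 with quantile normalization and 35 with robust variances. The PPP2CA difference of 0.07 became -0.038 with quantile normalization and -0.30 on the spike-in scale with or without the block, and ranged from -0.20 to 0.54 without 1 array. In the paired fit it became 0.31 with pair 1 left out, -0.043 with pair 2 left out and -0.062 with pair 3 left out. Detection calls were not used here, so how far signals below the filter level of 45.5 lie above background is not known.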

Other observations

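Gene families were picked by symbol after the calls were seen, and their enrichment was tested on the same calls, so what follows is descriptive. Of 8 measured metallothionein genes, which bind zinc and copper, 6 rose in the paired fit (MT1G, MT1H, MT1HL1, MT1X, MT2A, MT3; Fisher's exact test, adjusted p = 9.10e-09 over 14 tests), by 1.27 to 1.68 on the log2 scale. All 4 measured small proline-rich genes rose (SPRR1A, SPRR1B, SPRR2B, SPRR3; adjusted p = 5.98e-07), with SPRR2B up by 2.79 and SPRR1A by 3.06. Members of both families are related in sequence, which was not compared here, so their probe sets may share signal and may not count as separate evidence. Among 31 interleukins, chemokines and their receptors 6 rose (CCL22, CXCR4, IL18, IL1R2, IL6R, IL7R; adjusted p = 5.75e-05), with IL7R up by 5.87 from a control mean of 3.91 and IL6R by 2.68. In that family 11 rose and 2 fell with both number 1 arrays left out.

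Among genes that fell were 4 of 15 glutathione transferases (GSTK1, GSTM1, GSTM2, MGST3; adjusted p = 0.000568), 3 of 14 HOX genes (HOXC13, HOXC6, HOXD4; adjusted p = 0.00532) and both monoamine oxidase genes (adjusted p = 0.00106), with MAOA at -1.63 and MAOB at -3.49, which is imprecise since its mean after 8-Br-cAMP (4.23) lies below the filter level, as do the control means of IL7R and CCL22 and the IFI44L mean after 8-Br-cAMP. Interferon-induced genes went both ways: IFI44, IFI44L and EIF2AK2 fell and OAS1 rose among 21 measured (adjusted p = 0.0151 for the falls and 0.537 for the rise). With both number 1 arrays left out, 3 of these rose and 8 fell. In the same setting 1 glutathione transferase rose and 9 fell, and likewise 1 HOX gene rose and 9 fell.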
